A study of Mus musculus with 4 samples.

How the data were processed

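Small RNA sequencing of mouse sperm was compared between 2 control libraries and 2 libraries from mice labelled Mdd, a group exposed to varied daily stressors. The labels' protocols describe RNA extracted from sperm with TRIzol, selection of short RNA and a MGIEasy library kit, whereas the tissue field names testis and testicular cells. The description here follows the protocol and calls the material sperm. Nothing in the labels says that the replicates were separate animals, so p-values measure only the spread between these samples, which may be technical.

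Per the file headers, the authors collapsed identical reads to 1 row per distinct sequence of 15 to 45 nt and gave each row a raw read count, a length, a mark for a match to the genome and an annotation. The deposited counts were used as they are. Per the submitters' processing notes, DESeq2 and the mm9 build were used, with no version given. The aligner, adapter trimming and annotation databases are not given in the sources used here. miRNA annotations name hairpins and not mature arms, although the test had been planned on mature names. Counts were therefore summed per hairpin name with copy numbers removed, and reads that fit several hairpins kept a joint name such as miR-133a/miR-133b.

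Row identifiers were specific to a sample, so the tables were joined by sequence. The file of Mdd replicate 1 used fewer annotation classes than the other 3: it held miRNA, tRNA, piRNA and nuclear rRNA names only. Each sequence therefore took its annotation from the first library that gave one. This lowered the unannotated share of Mdd replicate 1 from 31.0% to 17.2% of reads and left the other 3 libraries as they were. Between the other files the annotations of shared sequences were the same in at least 99.99% of cases, against 90.4% to 91.3% with Mdd replicate 1. Unannotated reads entered the class shares and not the count tests.

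The files held 12845403 and 22948488 reads for control replicates 1 and 2, and 24031479 and 24112532 for Mdd replicates 1 and 2. miRNA reads numbered 80923, 286864, 203531 and 96048 in the same order. The 95% Wilson interval of a class share spanned at most ± 0.0243 percentage points with reads as the unit. Beyond a minimum at 3, 3, 11 and 4 copies, the smoothed number of genome-matched sequences at each copy number peaked at 7, 10, 38 and 8 copies, so reads are not independent molecules. With reads divided by that number it spanned at most ± 0.104 percentage points. Intervals and the floor of 3 counts per library cover counting error only. The floor is also given multiplied by that number for the called miRNA, for the miRNAs of lowest p on the positive side and for limits on single sequences. It is not so multiplied for list and tRNA group means.

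Counts were tested with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors are the log2 fold change divided by the root of the F statistic. CPM of a miRNA uses the total of miRNA reads, that of an annotated sequence the total of annotated reads, and CPM of all reads the library total. miRNA lists and tRNA groups with at least 3 tested members were tested with camera in limma 3.58.1, on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation. Shares and lengths were compared by an exact two-sided permutation test, whose smallest p for 2 against 2 samples is 0.333. Groups do not overlap by chance in 33.3% of such comparisons. Python 3.11.15, pandas 2.3.3 and scipy 1.17.1 were used for tables. The lists were let-7, miR-34 and miR-449, the X-linked cluster, miR-17-92, miR-10, miR-30, miR-29, miR-15 and miR-16, broadly expressed miRNAs, the Dlk1-Dio3 and Sfmbt2 clusters, miRNAs from earlier work on stress, and markers of epithelial, blood, muscle and stromal, gonadal somatic and neural cells.

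Design, lists, alternatives and the rule for named miRNAs were fixed before the data were examined. The rule took, in each direction, up to 12 miRNAs past the threshold with no overlap between groups, or, where fewer than 5 passed, the 5 of lowest p, with values only. It added the 8 of highest mean CPM, up to 4 members per list, and in other classes up to 4 that passed per direction and the 3 sequences of highest mean CPM. Alternatives fixed in advance were RLE scaling, library size only, DESeq2 1.42.0, no filter, a mean CPM of at least 10, robust dispersion, the replicate number as a block, the library size of all classes, hairpin names unsummed, fry for the lists and each sample left out. A minimum length of 18 nt, alone and with other choices, was chosen after seeing the data, as were counts summed per annotation name, annotation as deposited and counts divided, or the floor multiplied, by the copy number above.

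The count fits were tested on simulated data. Changed miRNAs and sequences were drawn only from those with an expected mean of at least 50 reads. The shifted sets for camera were likewise drawn from well-read miRNAs only. The rates below therefore do not cover features with fewer reads. For miRNAs with a dispersion of 0.2, 52% of 4-fold changes (256 miRNAs tested) and 100% of 16-fold changes (273 tested) were recovered among 50 changed. At a dispersion of 0.8, near the 0.82 estimated here, the shares were 0% (255 tested) and 38% (277 tested). For all sequences at a dispersion of 2, near the 1.94 estimated here, 0% of 200 changed sequences were recovered at either size (93942 and 97325 tested). Camera was run at a simulated dispersion of 0.2 only, with miRNAs varying independently. It found 40 of 40 sets of 10 miRNAs shifted 4-fold and called 3 of 40 unshifted sets. These rates do not carry over to the dispersion of 0.82 estimated here or to lists whose members vary together. Positions of miRNA hairpins come from an exact match of the most read sequence to GENCODE M21 on GRCm38 and were not converted from the authors' build.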

Results

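Sperm small RNA was profiled in 4 mouse libraries of the C57BL strain, 2 from undisturbed controls and 2 from mice of the Mdd group. The Mdd mice had been given a changing series of daily stressors, a treatment used to produce depressive-like behaviour, and the study asked how short non-coding RNAs of sperm differ after it. Total reads were 12845403 and 22948488 in control replicates 1 and 2 and 24031479 and 24112532 in Mdd replicates 1 and 2, the order kept below. Between 58.0% and 68.8% of reads matched the genome.

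tRNA fragments, nuclear rRNA fragments and piRNA-labelled reads were the main annotated RNA classes in every library. tRNA reads made up 27.0% and 28.5% of the control libraries and 23.1% and 19.8% of the Mdd libraries (27.8% ± 1.05 against 21.5% ± 2.35, SD, n = 2 each). Nuclear rRNA reads took 22.6% and 27.95% against 23.1% and 36.9%, and piRNA-labelled reads 23.4% and 21.6% against 21.9% and 16.8%. Mitochondrial rRNA varied within both groups, at 7.60% and 3.73% in controls and 9.29% and 3.89% in Mdd. miRNA hairpins accounted for only 0.630%, 1.25%, 0.847% and 0.398% of reads in control replicates 1 and 2 and Mdd replicates 1 and 2. The groups did not overlap for 3 of the 10 classes, tRNA, mitochondrial tRNA and unannotated reads, where chance gives 33.3% of classes, each with an exact permutation p of 0.333, the smallest that 2 against 2 samples allow. The file of Mdd replicate 1 named only 4 classes, and 10.2% of its reads lay in sequences found in no other file, so its unannotated share is an upper bound and its mitochondrial tRNA share a lower bound. With reads of 18 nt or longer, tRNA shares overlapped (21.6% and 26.6% against 22.8% and 19.3%), while piRNA shares did not (25.6% and 24.1% against 21.9% and 16.7%).

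**Figure D1:**
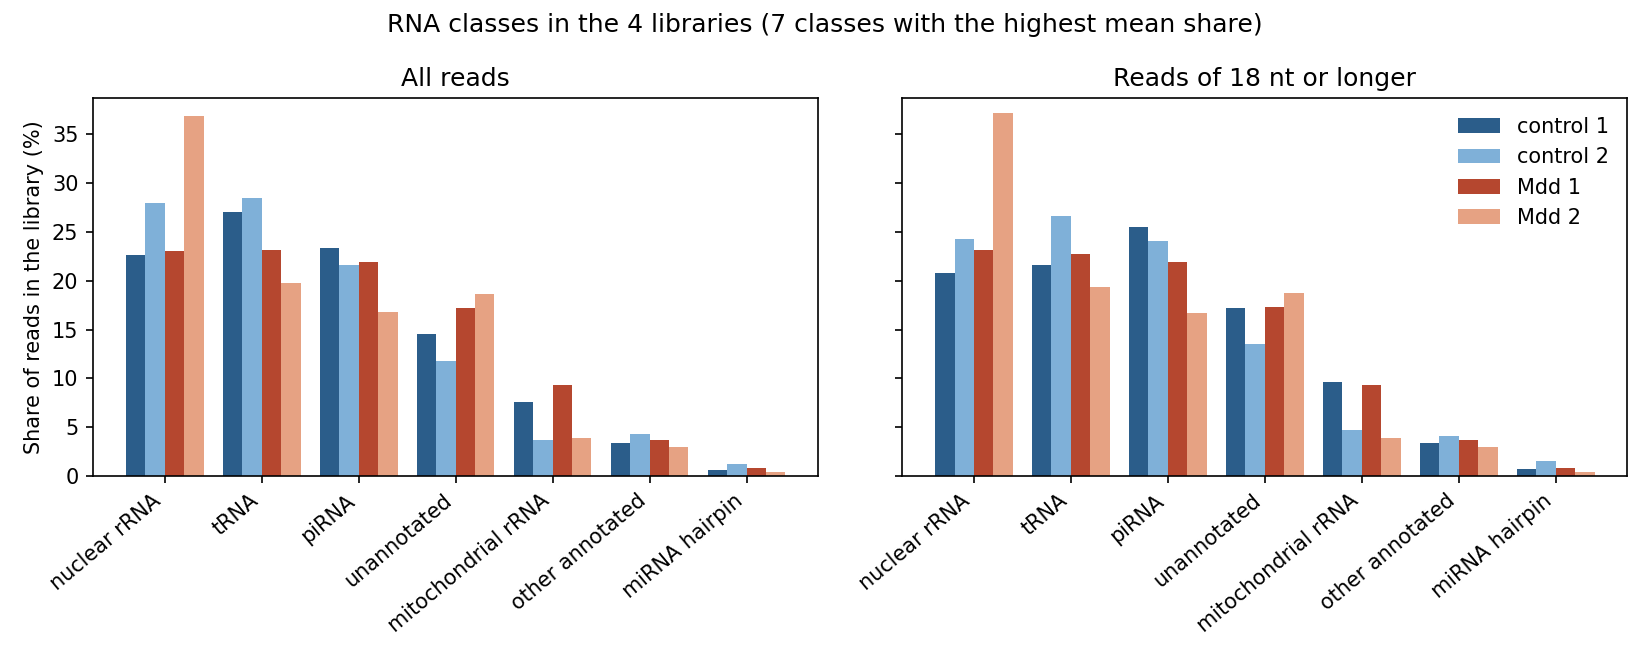
Share of reads (%) taken by the 7 most abundant RNA classes in each of the 4 libraries, for all reads and for reads of 18 nt or longer; each bar is 1 library. tRNA shares of 27.0% and 28.5% in controls stand above 23.1% and 19.8% in Mdd for all reads, and overlap among reads of 18 nt or longer.

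Mdd libraries had longer reads, with means of 26.4 and 26.7 nt against 24.2 and 23.2 nt in controls, a difference of 2.84 nt (exact permutation p of 0.333, the smallest possible). Reads of 15 to 17 nt made up 24.4% and 27.0% of the control libraries and 1.18% and 1.27% of the Mdd libraries. The labels' protocols describe RNA selected from 18 nt upward. Among reads of 18 nt or longer the mean lengths were 27.0 and 25.99 nt in controls and 26.5 and 26.9 nt in Mdd, which overlap. Several abundant short fragments lay wholly in the control libraries. CCGTACGGGCCACCA, a fragment of tRNA-Ile-AAT, had 365284 and 415811 reads in controls and 0 in both Mdd libraries. CGACTCTTAGCGGTG, annotated to 45S rRNA, had 144016 and 591980 reads against 0 and 0. A count of 0 allows up to 0.125 and 0.124 CPM of all reads in Mdd replicates 1 and 2 with each read taken as independent. With the usual copies per sequence it allows 4.74 and 0.995 CPM. Both fragments are 15 nt long, and reads of 15 to 17 nt are nearly missing from both Mdd libraries. These limits therefore do not bound a change of the fragments in sperm. Another 15 nt fragment, GACCGCGTGGCCTAA, the 5′ end of tRNA-Arg-TCG, was named after its values were seen. It had 2609 and 2422 CPM of all reads in controls and 2726 and 3457 in Mdd. The short reads that remain in Mdd may come from a later trimming of TGG ends, as described below. These values therefore do not show that this fragment was kept in sperm.

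**Figure D2:**
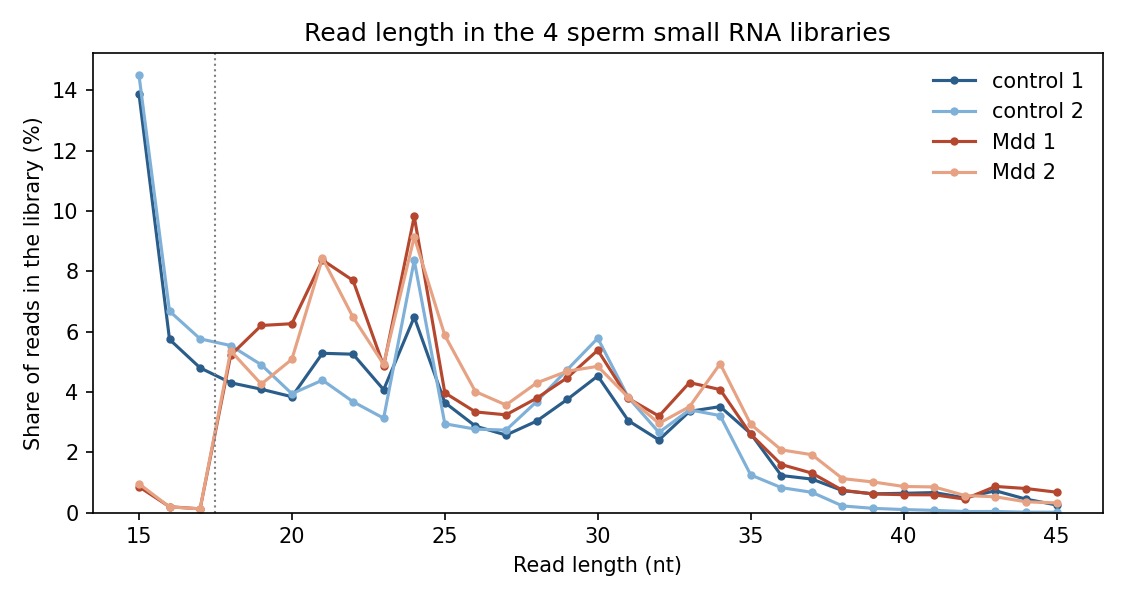
Share of reads (%) at each length from 15 to 45 nt in the 4 libraries, 1 line per library; the dotted line lies between 17 and 18 nt. Reads of 15 to 17 nt sum to 24.4% and 27.0% in controls and to 1.18% and 1.27% in Mdd.

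Among tRNA reads, 5′ ends were the largest part, at 59.0% and 73.5% in controls and 71.1% and 69.8% in Mdd. tRNA-Lys, tRNA-Val and tRNA-Glu fragments were abundant in all libraries. tRNA-Glu took 13.1% and 8.40% of control tRNA reads and 18.2% and 17.7% of Mdd tRNA reads, but 20.1% and 11.6% against 18.7% and 18.4% among reads of 18 nt or longer. tRNA-Ile took 11.1% and 7.04% of control and 0.789% and 0.418% of Mdd tRNA reads, but 0.753% and 0.880% against 0.787% and 0.395% at 18 nt or longer. Mdd replicate 2 stood apart at that length, with tRNA-Leu at 14.2%, tRNA-Ser at 11.4% and tRNA-Trp at 6.62% of tRNA reads. The other 3 libraries held at most 3.85%, 4.21% and 1.83% of these.

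Of 21 tRNA groups by amino acid, 2 passed camera with the preset correlation. Neither passed with an estimated correlation (adjusted p = 0.926 for both). With the preset one tRNA-Glu ranked higher in Mdd (adjusted p = 0.0107), with a median log2 fold change of 0.37 and a mean of -0.76 over 850 sequences. tRNA-Cys was lower (adjusted p = 0.0240, median -1.68 and mean -3.42 over 96 sequences). With sequences at 0 in a whole group placed at their bound of 3 reads per library both medians are the same, and the means become -0.17 and -1.82. tRNA-Glu had a median of 0.56 and a mean of 0.35 at 18 nt or longer, and tRNA-Cys -0.84 and -1.34, with 6 of 69 tRNA-Cys sequences at 0 in Mdd against 31 of 96 over all lengths. Reads of 18 nt or longer gave 5 groups: tRNA-Val, tRNA-Cys, tRNA-His and tRNA-SeC lower and tRNA-Glu higher, and again 0 with an estimated correlation (adjusted p = 0.974 for all 5). Over all lengths camera called 0 groups without Mdd replicate 2, tRNA-Ala alone without control replicate 2, 4 groups without Mdd replicate 1 and 3 without control replicate 1.

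miR-34b, a member of the miR-34 and miR-449 family of meiotic and later germ cells, had the highest mean CPM of the miRNAs, at 165182 and 44868 CPM in controls and 204780 and 150310 CPM in Mdd (log2 fold change 0.88, SE 1.13). In GRCm38 its hairpin lies on chromosome 9 from 51103562 to 51103645. miR-143, a smooth muscle miRNA on chromosome 18, stood at 39494 and 60077 CPM in controls and 39979 and 54650 in Mdd, and was above miR-34b in control replicate 2. miR-191 averaged 34944 ± 1297 in controls against 46844 ± 18665 CPM in Mdd (SD, n = 2 each), and miR-449a 37485 ± 9322 against 37455 ± 7516 CPM. The X-linked miR-465a/miR-465b/miR-465c averaged 38892 ± 25930 against 39574 ± 24899 CPM. The erythroid miR-451a stood at 40446 and 5156 CPM in controls and at 56213 and 46768 CPM in Mdd. miR-92a and let-7a completed the 8 of highest mean CPM, with log2 fold changes of 0.90 (SE 0.68) and 0.36 (SE 0.78). The fold changes of miR-143, miR-191, miR-449a and miR-465a/miR-465b/miR-465c changed sign with the library size of all classes, and those of miR-143 and miR-449a also with library size only. Group differences of these 8 did not pass the test (lowest adjusted p = 0.872 with edgeR).

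Of 248 miRNAs tested with edgeR's quasi-likelihood test, 1 was lower and 0 higher in Mdd at an adjusted p under 0.05, while 30 had an unadjusted p under 0.05. DESeq2 called 14, 1 higher and 13 lower. The call was the joint label miR-3473b/miR-3473e, with 370 and 1321 reads in controls and 0 and 0 in Mdd (fitted log2 fold change -12.52, SE 1.09, adjusted p = 0.0357, lower in 2 of 2 Mdd libraries). Its control mean stood 199.6-fold above a floor of 3 counts per library, with each read taken as independent. It stood 11.3-fold above that floor multiplied by the usual copies per sequence. All of the label's reads were 15 to 17 nt long, lengths nearly missing from both Mdd libraries, so neither fold bounds a change of this miRNA. Its most read sequence matched 17 annotated hairpins. Among reads of 18 nt or longer it had 0 reads in every library, and there edgeR called 0 of 236 miRNAs (lowest adjusted p = 0.158; 11 at an unadjusted p under 0.05) and DESeq2 7, 2 higher and 5 lower. Over all lengths edgeR gave the label an adjusted p of 0.459 without Mdd replicate 1 and 0.0528 without Mdd replicate 2, within a range of 6.74e-13 to 0.459 over the alternatives run. The count of calls was 12 without control replicate 1, 5 without control replicate 2 and 0 without either Mdd library, and at 18 nt or longer 7, 0, 5 and 16 without control replicates 1 and 2 and Mdd replicates 1 and 2.

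The next lowest p-values on the negative side did not pass with edgeR (adjusted p = 0.152 to 0.331), while DESeq2 called all 4 of these miRNAs (adjusted p = 1.53e-06 to 0.000104). miR-3470a/miR-3470b had 171 and 443 reads against 0 and 0, and the joint label let-7a/let-7b/let-7c 69 and 419 against 0 and 0, again from 15 to 17 nt reads alone. miR-320, with 200 and 137 reads against 2 and 0, drew 61.1% of its reads from those lengths. miR-133a/miR-133b, a striated muscle miRNA, had 26 and 1038 reads against 0 and 1 (log2 fold change -8.63, SE 2.07, adjusted p = 0.331 with edgeR), and 0.939% of its reads were that short. On the positive side, miR-669a/miR-669o had 0 and 1 reads in controls against 49 and 17 in Mdd (6.20, SE 2.08). The neuronal miR-124 had 79 and 182 reads against 1818 and 139 (2.85, SE 0.99), or 976 and 634 against 8932 and 1447 CPM. Of the 5 tested members of the neural list, 3 had positive and 2 negative fold changes. miR-3535 had 12 and 161 reads against 190 and 391, and miR-192 65 and 181 against 399 and 229. miR-7229 had 3 and 81 reads against 88 and 247. The most read sequence of miR-3535 and that of miR-7229 were 28 nt long, with 10.2% and 36.5% of the reads of each label. Those of miR-669a/miR-669o, miR-124 and miR-192 were 21 to 23 nt long. The floor multiplied by the usual copies per sequence is 114 and 24 reads in Mdd replicates 1 and 2. Both Mdd values of miR-669a/miR-669o and the 88 reads of miR-7229 lie below it. The 5 miRNAs on the positive side had adjusted p-values of 0.371 to 0.475 with edgeR, and DESeq2 called miR-124 alone (adjusted p = 0.0452).

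Neither list of germ cell miRNAs passed. All 4 members of the miR-34 and miR-449 list had positive fold changes with TMM (median log2 1.03, adjusted p = 0.362 with camera). With library size only, with the library size of all classes and at 18 nt or longer 3 did, with medians of 0.93, 0.26 and 0.90. The list held 104450 CPM in control replicate 2, against 210076 in control replicate 1 and 265940 and 227813 in Mdd, and without control replicate 2 its median was 0.66 (adjusted p = 0.592 with camera). Among them miR-34a stood at 3868 and 7913 CPM in controls and 10485 and 15284 in Mdd, and miR-34c at 10133 and 7592 against 7905 and 30079. The X-linked cluster, expressed in testis, had 14 of 15 members on the positive side with TMM (median log2 0.45, adjusted p = 0.253 with camera) and 4 of 15 with the library size of all classes. Its members miR-470 and miR-871 had log2 fold changes of 0.62 (SE 0.69) and 0.43 (SE 0.47). Camera called 0 of the 17 lists, with 2 at an unadjusted p under 0.05, and fry called 0 (lowest camera adjusted p = 0.253, and 0.823 with an estimated correlation).

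Of the 13 miRNAs that earlier work connected with stress in male mice, 9 had positive and 4 negative fold changes with TMM, and 5 and 8 with the library size of all classes. With edgeR 0 passed over all miRNAs or adjusted over the list alone, and 1, miR-193a, had an unadjusted p under 0.05; with the library size of all classes 1 passed either way. miR-193a passed with DESeq2 (adjusted p = 0.00368), but 96.7% of its reads were 15 to 17 nt long, and it had 0 and 9 control reads at 18 nt or longer. miR-375 in that list stood at 10961 and 4957 CPM in controls against 12190 and 8485 in Mdd. The median log2 fold change was 0.15. The mean was -0.26, and 0.12 with miR-193a, at 0 reads in Mdd, placed at its bound of 3 reads per library. Among reads of 18 nt or longer the median was 0.18 and the mean 0.42.

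The list of muscle and stromal miRNAs, which marks other cell types, had 8 of 11 members on the negative side (median log2 -2.19, adjusted p = 0.253 with camera). miR-1a, a striated muscle miRNA, stood at 1125 and 28578 CPM in controls and 1002 and 833 CPM in Mdd. miR-206 of skeletal muscle had 643 and 14997 against 413 and 10.4 CPM, and the endothelial miR-126a 3633 and 12306 against 2280 and 854 CPM. With edgeR 0 of 11 passed over all miRNAs and 0 adjusted over the list alone, with 5 at an unadjusted p under 0.05; adjusted over the list alone 6 passed with RLE scaling, 2 with library size only and 6 with the library size of all classes, which also gave 4 over all miRNAs. At 18 nt or longer 0 passed over all miRNAs and 5 of 10 adjusted over the list alone: miR-133a/miR-133b, miR-133a, miR-1a, miR-206 and miR-126a. Without control replicate 2 that count was 0, and the median over all lengths was -0.09 (adjusted p = 0.805 with camera). Without control replicate 1 the median was -3.94, and 5 of 12 passed over all miRNAs and adjusted over the list alone. Without Mdd replicates 1 and 2 over all lengths 0 passed over all miRNAs, and 0 and 2 adjusted over the list alone. At 18 nt or longer the counts over all miRNAs were 5, 0, 2 and 4, and adjusted over the list alone 6, 0, 6 and 4, without control replicates 1 and 2 and Mdd replicates 1 and 2. The summed list held 60984 and 178349 CPM in controls and 57205 and 74369 CPM in Mdd. The blood list held 42028 and 6212 CPM against 58571 and 49267, so control replicate 2 stood apart in both summed lists. Most of the blood sum was the erythroid miR-451a, at 40446 and 5156 CPM in controls and 56213 and 46768 in Mdd. Of the other tested members, miR-150 and miR-223 were highest in control replicate 2, miR-486a/miR-486b was lowest there and miR-142a neither. Blood members had 2 positive and 3 negative fold changes.

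**Figure D3:**
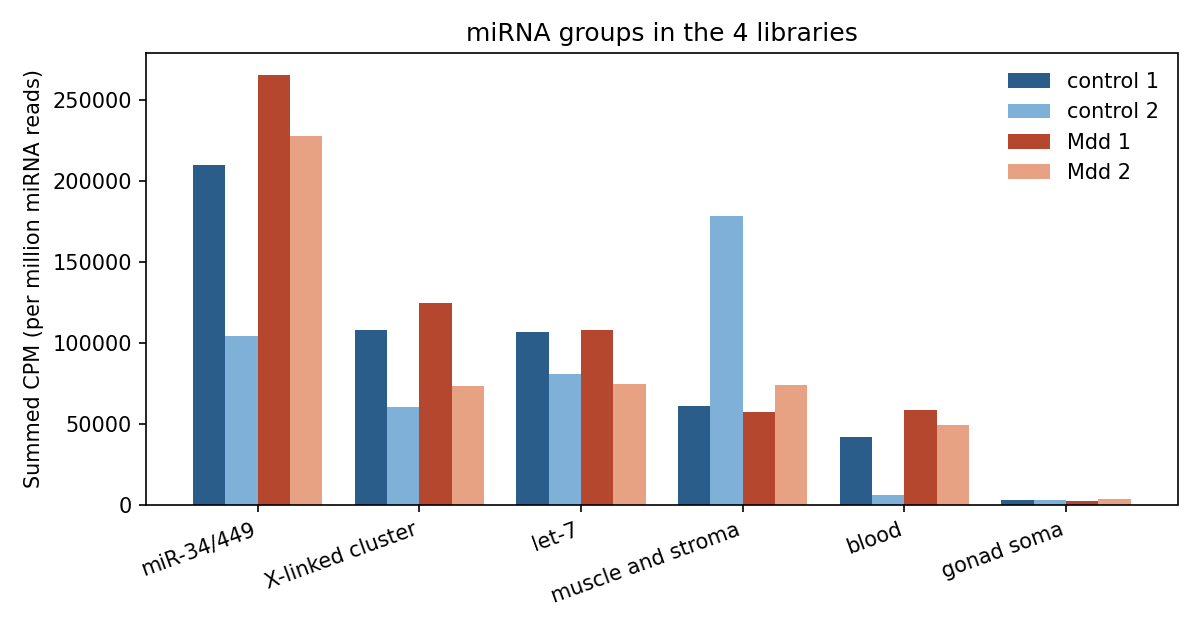
Summed CPM of miRNA reads for 6 miRNA lists in each of the 4 libraries; each bar is 1 library. The muscle and stroma list reaches 178349 CPM in control replicate 2 and 57205 to 74369 in the other 3, and the blood list is lowest in that library at 6212.

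let-7 miRNAs had 5 positive and 6 negative members with TMM, and 2 and 9 with the library size of all classes, where 1 passed over all miRNAs. With edgeR 1 passed adjusted over the list alone, the joint let-7a/let-7b/let-7c label, and 0 without control replicate 2 or Mdd replicate 1. let-7c stood at 26457 and 13184 CPM in controls against 22881 and 21958 in Mdd. With TMM and all samples the remaining lists had 0 members past the threshold with edgeR, over all miRNAs or adjusted over the list alone, with at most 2 members each at an unadjusted p under 0.05. With 1 sample left out the highest counts among them were 2 over all miRNAs, and 3 adjusted over the list alone for the miR-15 and miR-16 family without Mdd replicate 2. The miR-15 and miR-16 family had 0 of 6 and miR-29 0 of 3 positive members under every scaling run, but without control replicate 2 the former had 2 of 6 (median log2 -0.06), and 3 of 6 at 18 nt or longer, and the latter 0 of 3 with a median of -0.12. The abundant broadly expressed miRNAs had 4 of 16 positive members with TMM and 1 of 16 with the library size of all classes, where 1 passed. In the same order miR-10 had 2 and 0 of 7, gonadal somatic miRNAs 2 and 1 of 5 and neural miRNAs 3 and 3 of 5. The miR-17-92 group had 5 of 6 positive members with TMM and 1 of 6 with the library size of all classes, and the epithelial miR-200 group 8 and 3 of 11. In the same way miR-30 had 3 and 2 of 5, the Sfmbt2 cluster 9 and 6 of 17, and the imprinted Dlk1-Dio3 cluster 6 of 12 and 4 of 13.

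At the level of single sequences, tRNA-Lys-TTT and tRNA-Met-CAT 5′ fragments were among the most abundant. GCCCGGATAGCTCAGTCGGTAGAG of tRNA-Lys-TTT had a log2 fold change of -0.21 (SE 1.61), and GCCTCGTTAGCGCAGTAGGTAGCG of tRNA-Met-CAT 0.22 (SE 1.45). A 5.8S rRNA, a 28S rRNA and a mitochondrial rRNA fragment were among the 3 most abundant of their classes, with log2 fold changes of -0.31, 0.53 and 1.28 (SE 1.23, 1.22 and 1.30). Of 87781 annotated sequences, edgeR called 0 (lowest adjusted p = 0.142), although 22027 had an unadjusted p under 0.05, and 10875 of these were 15 to 17 nt long. DESeq2 called 7326, 721 higher and 6605 lower, of which 5853 were 15 to 17 nt long. At 18 nt or longer edgeR called 0 of 79093, with 10486 at an unadjusted p under 0.05. There DESeq2 called 198, of which 141 were higher and 57 lower in Mdd. DESeq2 gave no adjusted p for 34038 of the 87781 sequences and 52137 of the 79093, so its counts rest on fewer sequences. With 1 library left out edgeR called 1685 without control replicate 1, 1677 without control replicate 2, 7003 without Mdd replicate 1 and 5667 without Mdd replicate 2, with a lone library assumed to vary like the other group, and more of them lower than higher each time. The counts at 18 nt or longer were 15, 0, 2164 and 201 in that order, and of the 2164 without Mdd replicate 1, 2090 were higher. The median log2 fold change of all sequences was -0.35 with TMM and -0.25 with RLE scaling or library size. These medians include 11496 sequences of 15 to 17 nt, lengths nearly missing from both Mdd libraries. They are therefore no baseline for single changes at 18 nt or longer, where a median over all sequences was not taken.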

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

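All tests in this part were chosen after the results were seen. Reads with no annotation, which entered no count fit, averaged 17.9% of the Mdd libraries against 13.2% of the control libraries. Per library they were 14.6% and 11.8% in controls and 17.2% and 18.6% in Mdd, so both Mdd libraries lay above both controls. The value of Mdd replicate 1 is an upper bound, since its file named only 4 classes and 10.2% of its reads lay in sequences found in no other file. Among reads of 18 nt or longer the shares were 17.2% and 13.5% against 17.4% and 18.8%, a smaller gap.

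Reads of 15 to 17 nt were scarce in both Mdd libraries. Of the 17 nt sequences with at least 500 control reads, 89.1% had 0 reads in both Mdd libraries, against 0% at 18 nt, and the median log2 ratio of Mdd to control reads stepped by 10.13 between these lengths, which argues against physical size selection. Among short sequences whose parent RNA goes on with TGG, 17.8% were at 0 in Mdd, against 92.6% of the others. TGG was the rarest of the 64 final triplets in all 4 libraries. The short Mdd reads that remain may therefore come from a later trimming of TGG ends. Such trimming would give this contrast after a software cut and after a loss of short RNA in sperm alike, so the contrast cannot decide between them. The step of 10.13 also argues against a graded loss of short RNA in the sperm of stressed mice. Only a loss that stopped as sharply between 17 and 18 nt could give it. A loss that sharp and a minimum length of 18 nt applied to the Mdd reads by software both stay open. Some remaining short reads are not followed by TGG, and the cause of these was not tested.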

How the results depend on the processing

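Alternatives with a minimum length of 18 nt, copy numbers, annotation names or annotation as deposited were chosen after seeing the data. For miRNAs the call count of 1 became 2 with RLE scaling, 14 with DESeq2, 11 without a filter, 13 at a mean CPM of at least 10, 6 with robust dispersion, 12 with the library size of all classes, 11 with counts divided by copies (115 miRNAs tested against 248), 0 at 18 nt or longer, and 0 to 12 with 1 sample left out. With the library size of all classes 27.8% of miRNAs had positive fold changes, against 50% with TMM. It stayed at 1 with library size only and with hairpin names unsummed. At 18 nt or longer the count of 0 became 7 with DESeq2 and 0 to 16 with 1 sample left out. For all sequences the count of 0 became 7326 with DESeq2, 3290 without a filter, 1099 at a mean CPM of at least 10, 11 summed per annotation name (0 at 18 nt or longer), and 1677 to 7003 with 1 sample left out; it stayed at 0 with RLE, library size, robust dispersion and at 18 nt. At 18 nt or longer the count of 0 became 198 with DESeq2 and 0 to 2164 with 1 sample left out. A lone sample in a group is there assumed to vary like the other group. DESeq2 gave no adjusted p for 34038 sequences over all lengths and 52137 at 18 nt or longer. The cause of these shifts was not tested, although the number tested also differed without a filter, at a CPM minimum, with the library size of all classes, with names unsummed or summed per annotation, with counts divided by copies, at 18 nt or longer and with samples left out.

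The replicate number as a block gave 0 miRNA calls and 2632 sequence calls, and at 18 nt or longer 4 and 13. Same-numbered samples did not deviate together (r = -0.0512 for miRNAs, -0.0347 at 18 nt or longer and 0.0135 for all sequences, across features), so the numbers are not read as pairs. The block left 0 lists and 2 tRNA groups.

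Classes with no overlap between groups numbered 3, then 5 without the largest class and 6 by distinct features. The difference in mean length of 2.84 nt became 3.46 nt by distinct sequences and 0.207 nt at 18 nt or longer, and 2.35 to 3.34 nt with 1 sample left out. The 24 to 28 nt share turned to -0.489 points at 18 nt or longer. tRNA groups past the threshold went from 2 to 5 at 18 nt or longer, 0 with an estimated correlation at either length, and 0 to 4 with 1 sample left out. Lists stayed at 0 in each setting run. Of 335 values of 18 named miRNAs under alternatives, 288 kept their side of the threshold, 44 passed it and 3 no longer did; 28 changed sign, none of a called miRNA. At a simulated dispersion of 0.8, 16-fold miRNA changes were recovered in 38%; simulated depth was not varied.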

Other observations

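All tests in this part were chosen after the results were seen. rRNA and tRNA fragments of Mdd replicate 2 differed from those of the other libraries. 18S rRNA gave 39.1% of its nuclear rRNA reads at 18 nt or longer, against 19.3% to 22.6% in the other 3, and 4.5S rRNA 4.01% against at most 0.517%. 45S rRNA gave 6.25%, against 13.0% to 20.4%. Libraries correlated over 22147 sequences of 18 nt or longer at r = 0.755 between controls, 0.383 between the Mdd libraries and 0.722 between control replicate 1 and Mdd replicate 1, across sequences, which are not independent replicates.

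piRNA-labelled reads were of mixed kinds. Of those at 18 nt or longer, 37.2%, 22.2%, 37.1% and 55.7% lay 1 substitution from a tRNA or rRNA sequence of these libraries, in control replicates 1 and 2 and Mdd replicates 1 and 2. Reads of 26 to 32 nt with a 5′ T that matched the genome and were not near such a sequence made up 21.5%, 32.96%, 20.7% and 14.3%. A 5′ T was present in 79.0%, 83.6%, 79.1% and 70.6% of piRNA-labelled reads of 26 to 32 nt, against 24.4% to 35.5% of tRNA reads of that length.

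Muscle and stromal miRNAs lay lower in Mdd as a list, without passing the list test. Control replicate 1 held 60984 CPM of the list, between the Mdd values of 57205 and 74369, but 39494 CPM of this was miR-143, and without that miRNA it held 21490 CPM against 17226 and 19719 in Mdd. The median log2 ratio to the Mdd mean was 0.29 for control replicate 1, in which 7 of the 11 members were higher, and 2.97 for control replicate 2, with 10 of 11. Of the 11 members, 6 were higher in both controls than in both Mdd libraries and 0 lower: miR-1a, miR-126a, miR-206, miR-133a, miR-133a/miR-133b and miR-199b. Chance leaves groups apart in 33.3% of members, but members that vary together are not independent, so this count is no test. The labels miR-133a and miR-133a/miR-133b overlap, and miR-199b drew 50.9% of its reads from 15 to 17 nt. More muscle or stromal RNA in control replicate 2 alone and lower muscle and stromal miRNAs in the Mdd mice therefore both stay open, with 2 libraries per group.

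Reads ending in GG were frequent in Mdd replicate 2. They made up 30.1% of its annotated reads of 18 nt or longer, against 9.38%, 7.59% and 6.26% in the other libraries, and the share was highest there in 9 of the 9 annotated classes, which a preference for such ends in making that library could give. tRNA-Leu, tRNA-Ser and tRNA-Trp 5′ fragments not ending in GG were together 2.05 times the mean of the other libraries. The ratio was 2.75 for tRNA-Leu, 1.39 for tRNA-Ser and 1.33 for tRNA-Trp, so more of these fragments in that library also stays open, mainly for tRNA-Leu. These tRNAs were picked because they stood high in Mdd replicate 2, so a raised ratio is partly built in. In Mdd replicate 1 the same fragments together stood at 7784 CPM, between 6275 and 11960 in the controls.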
